A study of Sus scrofa with 81 samples.

How the data were processed

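The series profiled RNA from skeletal muscle of pigs of the breed labelled Landrance at 27 developmental stages, with 3 libraries per stage and 81 libraries in all. The stage names were read as day of gestation (E) and day after birth (D): 15 prenatal stages ran from E33 to E105 (45 libraries) and 12 postnatal stages from D0 to D180 (36 libraries). Per the labels' protocols, total RNA was isolated with TRIzol, depleted of ribosomal RNA, treated with DNase and made into strand-specific paired-end libraries. The labels do not name the muscle, the sex of the animals, a litter or a batch, and they do not say whether the libraries of a stage came from separate animals. All p-values therefore measure only the spread between these libraries, which may be technical.

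The deposited table holds FPKM (fragments per kilobase of transcript, relative to all mapped fragments) per gene and library, a unit normalized by the authors for transcript length and library size. Trimmomatic, HISAT2 2.0.4 and StringTie 1.3.1 are named in the submitters' processing notes. The genome build and annotation are not given in the sources used here, so no coordinates are printed. FPKM are shares of a library's total: when a few transcripts take more of the total, all others read lower without a change of their own. The table gives no read counts. Its low values (the smallest above 0 was 1e-06) were not tested for steps of whole reads, so the depth of each library remained unknown. No counting interval or detection limit was therefore computed, and precision rests on the spread between libraries alone.

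The table listed 28325 entries. Of these, 264 repeated one of 248 gene IDs with identical values and were dropped, which left 28061 genes, 5886 of them loci defined by the authors. Symbols were taken from the table. For 1522 genes with a blank symbol they came from a RefSeq gene table (assembly Sscrofa11.1, used for names only), in which all 22175 NCBI gene IDs were found. A further 25 symbols that had been turned into dates were restored, and 12 list members were found by product name. All 81 columns of values were matched to a library by the stage and replicate number in the column name.

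Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3; Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used to prepare tables. Genes with at least 1 FPKM in at least 3 libraries were tested, which kept 14220 genes and removed 13841. The model held 27 stage means fitted to all 81 libraries (54 residual degrees of freedom), with moderated variances that follow a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 together with an absolute log2 fold change of at least 1. The F test over all stages used the adjusted p alone. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM. Reads shared between near-identical genes, such as the myosin heavy chains, haemoglobins and ribosomal proteins with their pseudogenes, may have been split between copies by the quantification, so values of single members of such families are uncertain.

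The comparisons were the F test over the stages, postnatal against prenatal (mean of 12 stage means minus mean of 15), late fetal (E95, E100, E105) against early fetal (E33, E40, E45), D0 against E105, D9 against D0, late postnatal (D140, D160, D180) against early postnatal (D20, D30, D40), and the 26 steps between adjacent stages. Before the data were examined, these comparisons, their test, the alternatives that vary the pseudocount, filter, scaling, variance estimate, replicate block, libraries in the fit, fold change and left-out library, the rule for named genes and 30 gene lists were fixed. The lists were developmental contractile genes, fast-fibre contractile genes, slow-fibre contractile genes, excitation-contraction coupling genes, neuromuscular junction genes, myogenic regulators, cell cycle genes, extracellular matrix genes, glycolysis and glycogen genes, oxidative phosphorylation and TCA cycle genes, mitochondrially encoded genes, fatty acid oxidation genes, ribosomal protein genes, imprinted fetal growth genes, IGF and myostatin signalling genes, muscle protein breakdown genes, glucocorticoid response genes, immediate early genes, heat shock genes, circadian clock genes, interferon response genes, and markers of adipocytes, erythroid cells, leukocytes, endothelium, cartilage and bone, tendon, nerve and Schwann cells, liver and epidermis. None of the 13 mitochondrially encoded genes was among the genes tested, so 29 lists entered the tests.

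Lists were tested with camera, which asks whether members moved more than the other genes did, at a preset correlation between genes of 0.01 and again with an estimated correlation. The p-values were adjusted over the 29 lists of a comparison. Members called were counted after adjustment over all genes and, separately, adjusted over the list alone. The 2 counts were the same in 140 of 145 list tests, and the report gives the other 5. Named genes were, per comparison, the 5 called genes with the largest rise and the 5 with the largest fall among genes with a symbol, at least 5 FPKM on the higher side and no overlap between the libraries of the sides (at least 90% of pairs in order for postnatal against prenatal), 13 anchor genes (6 myosin heavy chains, PAX7, MYF5, MYOD1, MYOG, MYF6, IGF2 and MSTN), and up to 4 members with the largest change per list described. For adjacent stages the rule took the 3 steps with most calls, with 3 rises and 3 falls each, and for the F test the 10 genes with the largest range of stage means. Some genes that meet these rules are not reported here.

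The tests were checked on simulated data with 100 of the 14220 genes changed by 2-fold and 100 by 4-fold. With the fold change asked, 81 of the 4-fold and 6 of the 2-fold genes were recovered for postnatal against prenatal, 83 and 10 for late against early fetal, 81 and 16 for D0 against E105, 77 and 9 for D9 against D0, and 82 and 12 for late against early postnatal, with at most 1 false call in each. The F test recovered 90 and 41 with 9 false calls, and the step from D60 to D80 recovered 76 and 18 with 1. Camera recovered a changed cell cycle list with 0 of 28 other lists called. No correlated genes were simulated, so this gives no error rate for real libraries. Recoveries cover genes of all levels, many near 1 FPKM. On this scale 2-fold stays below 1.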

Results

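RNA levels were compared across 81 libraries of pig skeletal muscle, 3 at each of 27 stages from E33 of gestation to D180 after birth. The summed FPKM of a library ranged from 320339 to 452249. Libraries of the prenatal stages had 11928 ± 165.1 genes (SD, n = 45) at 1 FPKM or more and those of the postnatal stages 10390 ± 394.6 (SD, n = 36). The 10 most abundant genes held 13.5% ± 3.35 of the summed FPKM before birth and 27.5% ± 5.10 after it, and the ribosomal protein genes 22.8% ± 1.51 and 14.4% ± 2.44. The median gene was lower in the later samples of each comparison. The median log2 fold change over all genes tested was -0.55 for postnatal against prenatal, -0.19 for late against early fetal, -0.20 for D0 against E105, -0.17 for D9 against D0 and -0.05 for late against early postnatal. Scaling each library by the median ratio of its genes brought these medians to between -0.02 and 0.01, and the splits of higher and lower genes under that scaling are given beside the main ones.

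Libraries of a stage resembled each other closely. Pearson's r across the 14220 genes, which are not independent replicates, lay between 0.954 and 0.993 for the 81 pairs within a stage (median 0.986) and between 0.697 and 0.992 for pairs from different stages. The nearest library came from the same stage for 71 of the 81 libraries, from a neighbouring stage for 8 and from elsewhere for 2, and 0 of 3240 pairs held identical values. Principal component 1, with 67.5% of the variance, ran from E33, with a mean score of -92.0, to the postnatal stages, with the highest mean (81.9) at D120. Component 3, with 4.04%, set the 3 libraries of D0 apart, at scores of -75.5 to -55.4 against a mean of -23.7 at E33.

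**Figure D1:**
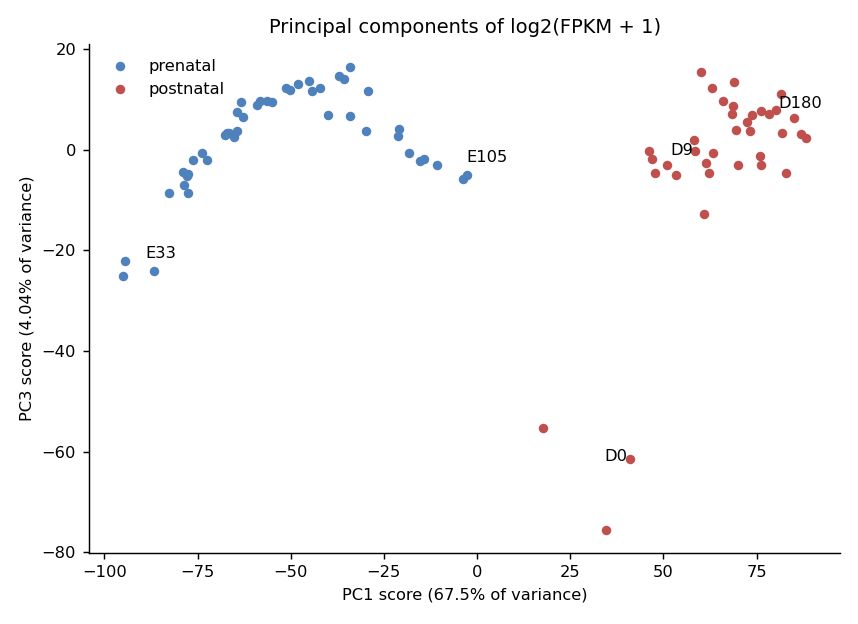
Scores of the 81 libraries on principal component 1 (horizontal) and 3 (vertical) of log2(FPKM + 1), with prenatal libraries in blue and postnatal libraries in red. Along component 1, libraries of E33 lie at the left and all postnatal libraries at the right, and the 3 libraries of D0 lie lowest on component 3, between -75.5 and -55.4.

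Which genes changed over development was asked first. By limma's moderated F test, 14120 of 14220 genes differed between stages. Of the 10 genes with the widest range of stage means, MYH4 (NCBI gene 100144306), the myosin heavy chain of the fastest fibres, went from 2.30 ± 0.570 FPKM (SD, n = 3) at E33 to 5543 ± 719 (n = 3) at D180 (adjusted p = 4.6e-41). ACTN3 (100519531), which anchors thin filaments in fast fibres, peaked at D140 with 1359.8 ± 69.1 FPKM, MYBPC2 (100511817), the fast myosin-binding protein, at D30 with 1066 ± 33.2 FPKM, and MYH1 (100125538), the heavy chain of 2X fibres, at D9 with 4876 ± 545 FPKM. CKM (397264), the muscle creatine kinase, and MYOZ1 (574060), a Z-disc protein of fast fibres, also peaked at D30, at 9042 ± 1052 FPKM and 1872 ± 331 FPKM. EEF1A2 (110257403), the adult muscle form of a translation elongation factor, peaked at D120 with 1141 ± 113 FPKM and CA3 (494016), a muscle carbonic anhydrase, at D160 with 2999 ± 203 FPKM. The atrial myosin light chains MYL4 (100516998) and MYL7 (100514437) were highest before birth. MYL4 was highest at E50 (469.7 ± 91.2 FPKM) and lowest at D160 (0.0557 ± 0.0964), and MYL7 was highest at E70 (397 ± 60.1 FPKM) and listed at 0 in all 3 libraries of D80.

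The myosin heavy chain genes peaked at different stages. MYH3, the embryonic form, stood at 1317 ± 121 FPKM (SD, n = 3) at E33 and 2030.0 ± 247 at E60, then at 89.7 ± 13.7 at E105 and 10.7 ± 3.09 at D30. MYH8, the perinatal form, was highest in mid to late gestation, with 2759.9 ± 477 at E75, and stood at 1361 ± 170.4 at E105, 457 ± 125 at D0 and 64.9 ± 19.8 at D30. MYH2, of fast oxidative fibres, reached 1182 ± 533 at D0, and MYH1 1331 ± 348 at E105 and 4876 ± 545 at D9. MYH4 stood at 15.3 ± 3.72 at E75, 353 ± 70.1 at D0 and 2936 ± 1345 at D9. MYH7, the slow form, had 117 ± 20.7 at E33, 541 ± 124 at E60, 1252 ± 598 at D9 and 289 ± 99.9 at D120. Of the 14120 genes called, 5067 (35.9%) peaked at E33, 1402 (9.93%) at D0 and at most 720 at any other stage, while 2964 (21.0%) were lowest at D120. These counts used the deposited scaling, and no other was tried.

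**Figure D2:**
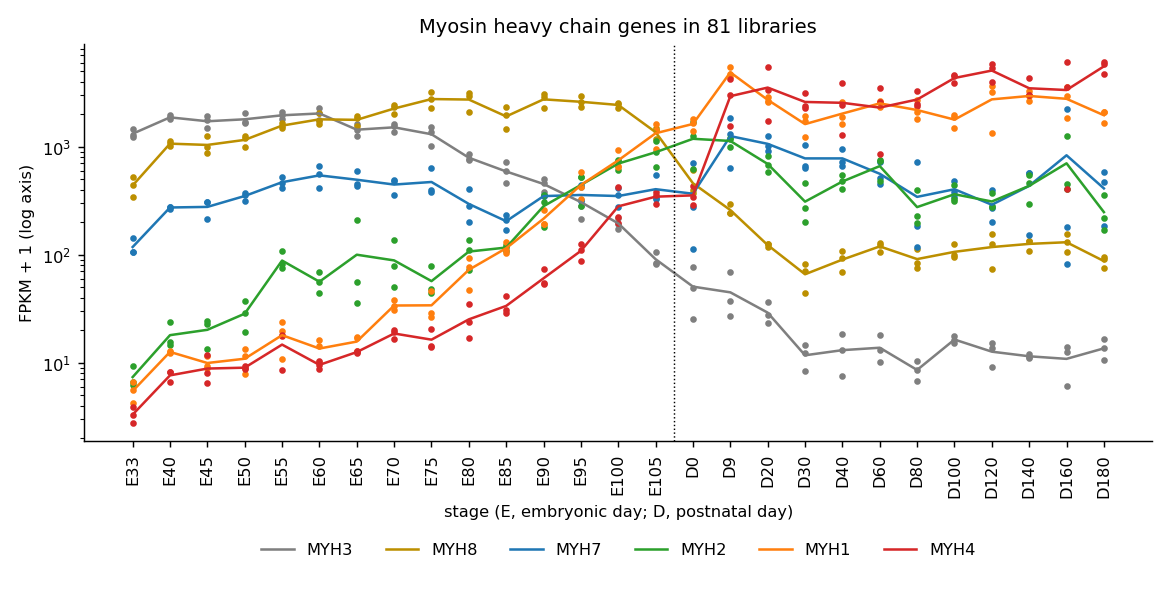
FPKM + 1 on a log axis (vertical) of 6 myosin heavy chain genes at the 27 stages (horizontal), with a point per library and lines through the stage means; the dotted line marks birth. MYH3 went from 2030.0 ± 247 FPKM (SD, n = 3) at E60 to 10.7 ± 3.09 at D30, and MYH4 from 15.3 ± 3.72 at E75 to 5543 ± 719 at D180.

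Adjacent stages, unequally spaced, differed most at the 2 steps that share D0. The steps from E105 to D0 (1729 genes, 395 higher and 1334 lower) and from D0 to D9 (1482; 709 and 773) held more calls than any other. The steps from D60 to D80 (539; 314 and 225) and from E33 to E40 (509) came next, and their order changed without replicate 1 of D80 (427 from D60 to D80) or replicate 2 of E40 (558 from E33 to E40). From E40 to E105 no step had more than 92 calls. The largest rises from D60 to D80 among the named genes included CXCL9 and CXCL10, chemokines induced by interferon gamma, with log2 fold changes of 3.995 ± 0.48 (SE), adjusted p = 7.5e-09, and 3.69 ± 0.65 (SE), adjusted p = 1.9e-05. JCHAIN, of plasma cells, had 4.15 ± 0.50 (SE), adjusted p = 5.9e-09, with 276.0, 32.6 and 13.2 FPKM at D80. SEs and p-values use the spread of all stages, not that of D80 or D0 alone. Lower at D80 than at D60 were ATF5, a transcription factor of the amino acid and stress response, from 80.1 ± 2.60 to 1.75 ± 0.473 FPKM (SD, n = 3 each; -4.90 ± 0.31 (SE), adjusted p = 1.0e-18), the mitochondrial arginase ARG2, from 107 ± 57.3 to 4.47 ± 3.03 FPKM, and FGF21, a hormone released by stressed muscle (-4.28 ± 0.55 (SE), adjusted p = 2.8e-08). The 26 steps gave 6093 calls, 2550 higher and 3543 lower, and 3482 higher and 2633 lower under median-ratio scaling. Leaving out 1 library moved the count of several steps by over 1.5 times. From E85 to E90 it was 92, and 140, 43 and 148 without replicate 1, 2 or 3 of E90. From D9 to D20 it was 40, and 86 and 21 without replicate 1 or 3 of D9 and 61 without replicate 1 of D20. From D30 to D40 it was 209, and 315 and 111 without replicate 2 or 3 of D30. From D100 to D120 it was 242, and 475 without replicate 3 of D120. From D120 to D140 it was 108, and 200 without replicate 2 of D140. From D160 to D180 it was 90, and 156 and 59 without replicate 1 or 2 of D160 and 55 and 56 without replicate 1 or 2 of D180.

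**Figure D3:**
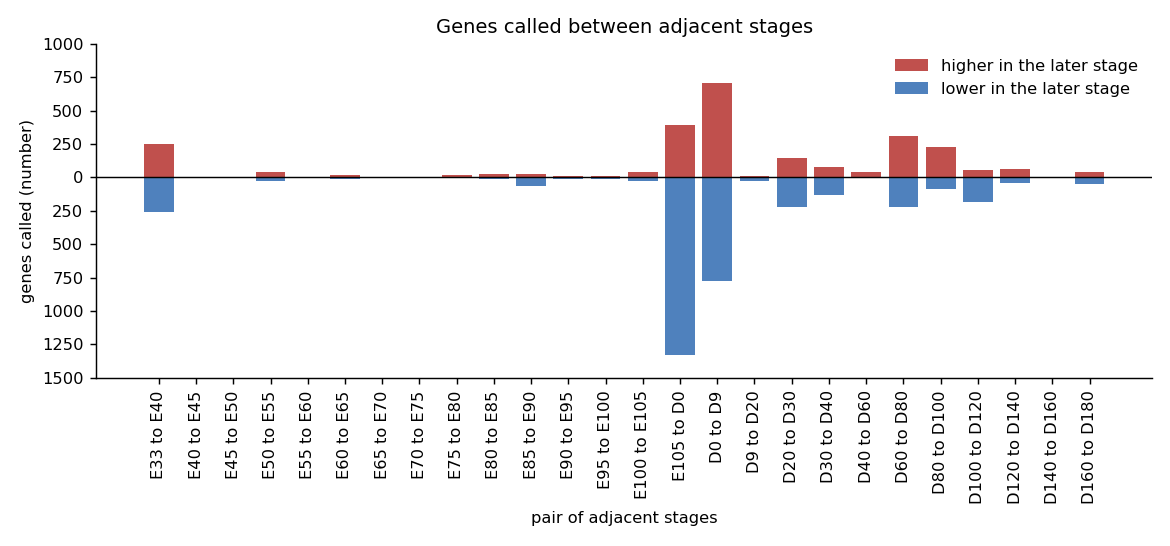
Number of genes called (vertical) at each of the 26 steps between adjacent stages (horizontal), with genes higher in the later stage above the line in red and genes lower in it below the line in blue. The largest bars are those of the step from E105 to D0, with 395 genes higher and 1334 lower, and from D0 to D9, with 709 and 773.

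Levels after birth were compared with those before it. All 15 measured fast-fibre contractile genes rose between the mean of the prenatal and the mean of the postnatal stages (camera, adjusted p = 1.9e-21, or 0.00296 with estimated correlation). MYH4 was at 3229 ± 1697 FPKM (SD, n = 36) after birth against 62.5 ± 107 (n = 45) before it (log2 fold change 6.75 ± 0.13 (SE), adjusted p = 1.7e-49), ACTN3 at 1019 ± 404 FPKM against 13.1 ± 16.2 (6.59 ± 0.088 (SE), adjusted p = 1.9e-57), MYBPC2 at 745 ± 287 FPKM against 14.9 ± 18.7 (6.48 ± 0.071 (SE)) and MYH1 at 2479 ± 971 FPKM against 204 ± 376 (5.58 ± 0.075 (SE)). EEF1A2 rose with them, to 805 ± 247 FPKM from 54.6 ± 66.9. Of the 8 developmental contractile genes 7 fell (camera, adjusted p = 0.0112, or 0.168 with estimated correlation), among them MYL4 (-6.84 ± 0.058 (SE), adjusted p = 1.2e-67), MYH3 (-5.74 ± 0.079 (SE)), the cardiac actin ACTC1 (-5.06) and the cardiac troponin TNNT2 (-4.93). MYL7 fell by 6.44 and ARHGAP36, a regulator of protein kinase A, by 5.58 on the log2 scale. Of the other anchors, MYH8 fell (-3.73) and MYH2 rose (2.48), while MYH7 was not called (0.51 ± 0.16 (SE)).

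Lists of energy metabolism rose after birth. Of 19 glycolysis and glycogen genes 15 rose (camera, adjusted p = 1.1e-23, or 0.00495 with estimated correlation): the muscle glycogen phosphorylase PYGM was at 1531 ± 595 FPKM (SD, n = 36) against 77.1 ± 47.5 (n = 45), and the log2 fold changes of PYGM, the muscle enolase ENO3, the phosphofructokinase PFKM and the lactate dehydrogenase LDHA were 4.37, 4.198, 3.84 and 3.81. Of 34 oxidative phosphorylation and TCA cycle genes 14 rose (camera, adjusted p = 1.2e-30, or 0.0174 with estimated correlation), led by the muscle cytochrome oxidase subunit COX7A1 (3.65 ± 0.064 (SE), adjusted p = 3.7e-51) and SUCLA2 (2.17). Of 19 fatty acid oxidation genes 4 rose (camera, adjusted p = 1.4e-10, or 0.0262 with estimated correlation): PDK4, UCP3, CD36 and ACADM. Under median-ratio scaling 33 oxidative phosphorylation and TCA cycle genes and 14 fatty acid oxidation genes were called higher and 0 lower. Of 16 excitation-contraction coupling genes 9 rose (camera, adjusted p = 3.1e-13, or 0.00495 with estimated correlation), for instance the calcium pump regulator SLN (2.31 ± 0.075 (SE)) and TRDN (2.13), and the chloride channel CLCN1 rose by 1.70. Slow-fibre contractile genes went both ways, with 1 of 12 higher (MYL3, 1.63) and 2 lower (CASQ2, -3.29; MYH7B, -1.63), a median of 0.24, camera's direction up, but a mean of -0.18 (camera, adjusted p = 0.025, or 0.53 with estimated correlation). Under median-ratio scaling 7 were higher and 2 lower.

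All but 1 of 13 imprinted fetal growth genes fell (camera, adjusted p = 0.00807, or 0.173 with estimated correlation), led by PEG10 (-5.51 ± 0.065 (SE), adjusted p = 3.3e-60), MEG3 (-3.68), MEST (-2.88) and DLK1 (-2.81). IGF2, the fetal insulin-like growth factor, was at 27.0 ± 23.9 FPKM (SD, n = 36) against 91.8 ± 21.0 (n = 45) (-2.19 ± 0.089 (SE), adjusted p = 4.6e-32). Of 17 IGF and myostatin signalling genes 9 fell, with IGFBP2 (-3.17), IGF2BP3 (-2.46) and MSTN, which restrains muscle growth (-1.88 ± 0.081 (SE)), but the list did not pass (camera, adjusted p = 0.311). Of 30 cell cycle genes 28 fell (camera, adjusted p = 1.8e-05, or 0.444 with estimated correlation), for instance TOP2A, which untangles DNA, from 48.0 ± 21.5 (n = 45) to 5.68 ± 4.49 FPKM (SD, n = 36) (-3.05 ± 0.077 (SE), adjusted p = 7.9e-43), and the cyclin CCNB1 (-2.61). Of 14 myogenic regulators 7 fell and 0 rose (camera, adjusted p = 0.182): MYF5 (-2.88 ± 0.064 (SE)), the fusion factor MYMK (-2.25), MEF2C (-2.04), and MYOG (-1.99 ± 0.056 (SE)) among them. PAX7, which marks satellite cells, fell by 1.65, MYOD1 had -1.11 but -0.34 under median-ratio scaling and -0.60 under quantile normalisation, which ended its call, and MYF6 was not called (0.49 ± 0.10 (SE)). Of 12 neuromuscular junction genes 11 fell (camera, adjusted p = 0.00655, or 0.173 with estimated correlation), including COLQ (-3.02) and the fetal acetylcholine receptor subunit CHRNG (-2.63). Of 27 extracellular matrix genes 19 fell (camera, adjusted p = 0.0477, or 0.599 with estimated correlation), including POSTN (-5.05 ± 0.13 (SE)) and FBN2 (-4.12). Of 38 ribosomal protein genes 10 fell (camera, adjusted p = 0.00779, or 0.599 with estimated correlation), with RPL3 at -2.33. Under median-ratio scaling 1 was higher and 1 lower. That scaling (and, for the first, quantile normalisation too) left 6 neuromuscular junction, 9 extracellular matrix and 5 IGF and myostatin signalling genes lower, and had 1 imprinted and 1 myogenic gene higher.

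All 7 tendon markers fell, as TNMD did (-4.97 ± 0.19 (SE)), but the list did not pass (camera, adjusted p = 0.179). Of 14 cartilage and bone markers 9 fell (camera, adjusted p = 0.151), among them COL2A1 (-4.47). Of 11 nerve and Schwann cell markers 4 fell (camera, adjusted p = 0.891), led by the neuregulin receptor ERBB3 (-3.67 ± 0.034 (SE)). Of 10 erythroid markers 6 fell (camera, adjusted p = 0.381), with HBB at 713 ± 635 FPKM (SD, n = 36) against 2769 ± 1606 (n = 45). Of 14 endothelial markers 2 fell, APLNR (-1.86) and KDR (-1.62; -0.85 and not called under median-ratio scaling), with a median of -0.36 where camera's direction was up (camera, adjusted p = 0.22). Under median-ratio scaling 2 were higher and 1 lower. Of 14 adipocyte markers 8 rose (camera, adjusted p = 1.5e-07, or 0.115 with estimated correlation), for instance PLIN4, a lipid droplet protein (2.86 ± 0.078 (SE)), and ADIPOQ (2.99). Of 19 leukocyte markers 7 rose (camera, adjusted p = 7.7e-10, or 0.163 with estimated correlation), with SLA-DRA of antigen presentation at 2.55 ± 0.089 (SE). Of 15 interferon response genes 10 rose (camera, adjusted p = 7.7e-10, or 0.167 with estimated correlation): ISG15 had 3.13 ± 0.25 (SE). Of the 9 liver markers only APOA1 was called (-1.31; -0.51 under median-ratio scaling, not called), and the list had a median of 0.09, a mean of -0.09 and camera's direction up (camera, adjusted p = 0.0271, or 0.503 with estimated correlation). None of the 3 epidermis markers was called by limma, with 3 at an unadjusted p below 0.05 (median -0.27, camera's direction up; camera, adjusted p = 0.16).

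Of 12 glucocorticoid response genes 4 rose (camera, adjusted p = 6.1e-08, or 0.0616 with estimated correlation), with KLF9 (2.78 ± 0.069 (SE)) and ZBTB16 (2.35). Of 16 muscle protein breakdown genes 3 rose (camera, adjusted p = 1.3e-06, or 0.0732 with estimated correlation): the muscle ubiquitin ligases FBXO40 (5.02 ± 0.056 (SE)) and TRIM63 (2.04) and the autophagy receptor SQSTM1 (1.20). Of 12 heat shock genes 5 rose (camera, adjusted p = 7.3e-04, or 0.223 with estimated correlation), HSPB7 (1.42) and HSPB1 (1.38) among them. Of 16 immediate early genes 2 rose, BTG2 and ATF3, and KLF6 fell (camera, adjusted p = 5.1e-05, or 0.173 with estimated correlation), a fall that was -0.45 under median-ratio scaling and -0.77 after quantile normalisation, not called in either. Of 15 circadian clock genes NR1D2 alone was called (1.13; camera for the list, adjusted p = 2.6e-05, or 0.0262 with estimated correlation). Under median-ratio scaling 9 glucocorticoid response, 8 muscle protein breakdown, 9 immediate early, 4 circadian clock and 11 leukocyte genes were called higher and 0 lower. By limma, 3781 of 14220 genes were called, 572 higher and 3209 lower after birth. This split depended on the scaling: 1486 genes were higher and 925 lower under median-ratio scaling, and 1173 higher and 1038 lower after quantile normalisation. Without the 3 libraries of D0, which lay apart from the others, 602 genes were higher and 3486 lower. Without them, endothelial markers had 1 higher and 2 lower.

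Extracellular matrix genes lost their list call with a mean of at least 1 FPKM, a pseudocount of 0.1 and scaling to equal sums (adjusted p = 0.0514 to 0.0757). Liver markers lost their list call with a mean of at least 1 FPKM, median-ratio scaling, no filter, a pseudocount of 0.1 and quantile normalisation (adjusted p = 0.0587 to 0.792). Ribosomal protein genes lost their list call with median-ratio scaling (adjusted p = 0.878). Slow-fibre contractile genes lost their list call with median-ratio scaling, no filter and quantile normalisation (adjusted p = 0.11 to 0.833). Heat shock genes lost their list call with quantile normalisation (adjusted p = 0.0739). Cartilage and bone markers and tendon markers passed as lists, lower, with median-ratio scaling, no filter and quantile normalisation (adjusted p = 5.1e-04 to 0.0302). Erythroid markers passed as a list, lower, with median-ratio scaling and quantile normalisation (adjusted p = 0.0225 to 0.0486). IGF and myostatin signalling genes and myogenic regulators passed as lists, lower, with no filter (adjusted p = 0.00866 to 0.0253).

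For gestation, the late fetal stages were compared with the early ones. Of 15 fast-fibre contractile genes 14 rose from the early (E33 to E45) to the late fetal stages (E95 to E105) (camera, adjusted p = 1.6e-16, or 0.0154 with estimated correlation): MYH1 from 8.32 ± 3.26 (n = 9) to 839 ± 439.9 FPKM (SD, n = 9) (log2 fold change 6.41 ± 0.16 (SE), adjusted p = 5.8e-42), MYH2 from 14.2 ± 7.10 to 675 ± 240.3 FPKM (5.55 ± 0.23 (SE), adjusted p = 6.6e-30) and MYH4 from 5.58 ± 2.92 to 243 ± 124 FPKM (5.16 ± 0.27 (SE)). The largest rise was that of ART3, an ADP-ribosyltransferase family member, from 0.289 ± 0.193 to 174 ± 64.3 FPKM (7.01 ± 0.14 (SE)), followed by MYH1, EEF1A2 (6.32) and the fatty acid carrier FABP4 (5.67). The largest falls were those of S100A7 (-5.35 ± 0.20 (SE)), the brain creatine kinase CKB (-4.75 ± 0.17 (SE)), MYL4 (-4.74), the neuronal stathmin STMN2 (-4.73) and OSTN, a muscle-secreted peptide (-4.49). Of 8 developmental contractile genes 4 fell, MYH3 with -3.22 ± 0.17 (SE), and MYH8 rose (1.39, but 0.97 and not called without the 3 libraries of E33). The list did not pass (camera, adjusted p = 0.0575).

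Of 19 fatty acid oxidation genes 14 rose (camera, adjusted p = 3.7e-12, or 0.0227 with estimated correlation), among them the muscle carnitine transferase CPT1B (2.91 ± 0.12 (SE)) and CD36 (2.57). Of 34 oxidative phosphorylation and TCA cycle genes 18 rose (camera, adjusted p = 7.2e-19, or 0.0915 with estimated correlation), COX7A1 from 16.4 ± 3.15 (n = 9) to 535 ± 271 FPKM (SD, n = 9). Of 19 glycolysis and glycogen genes 10 rose (camera, adjusted p = 1.1e-09, or 0.118 with estimated correlation), ENO3 by 4.02 and ALDOA by 2.55. Of 16 excitation-contraction coupling genes 11 rose (camera, adjusted p = 1.3e-09, or 0.0227 with estimated correlation), SLN by 3.03 and the calcium channel CACNA1S by 2.12. Of 15 circadian clock genes 5 rose (camera, adjusted p = 2.1e-05, or 0.0312 with estimated correlation), such as NR1D2 (2.85 ± 0.10 (SE)), BHLHE40 (2.83) and ARNTL (1.29). Among 12 slow-fibre contractile genes MYBPC1 rose (1.63) and MYH7B fell (-1.49; camera for the list, adjusted p = 0.193), and MYH7 was not called (0.82 ± 0.33 (SE)). Under median-ratio scaling 4 slow-fibre genes were higher and 1 lower.

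Of 30 cell cycle genes 26 fell (camera, adjusted p = 2.3e-10, or 0.327 with estimated correlation), with CCNB1 from 31.6 ± 3.81 (n = 9) to 6.42 ± 0.924 FPKM (SD, n = 9) and KIF20A at -2.27 ± 0.11 (SE). Of 12 neuromuscular junction genes 4 fell (camera, adjusted p = 0.0216, or 0.386 with estimated correlation): CHRNG (-3.84 ± 0.089 (SE)), MUSK (-2.36), CHRND (-2.31) and CHRNA1 (-2.14). Of 14 myogenic regulators MSC (-2.43) and MYF5 (-1.68) fell and the integrin ITGA7 rose (1.07, but 0.76 and not called without the E33 libraries; camera for the list, adjusted p = 0.53). MYOD1 had 0.03 ± 0.14 (SE), MYOG -0.44 ± 0.12 (SE), PAX7 -0.79 ± 0.11 (SE), MYF6 0.75 ± 0.21 (SE) and MSTN -0.92 ± 0.17 (SE), none of them called. Of 17 IGF and myostatin signalling genes 6 fell and 1 rose (camera, adjusted p = 0.124), with the RNA-binding proteins IGF2BP1 (-3.66 ± 0.041 (SE)), IGF2BP2 (-1.77) and IGF2BP3 (-1.76) lower, whereas IGF2 itself was not called (0.38 ± 0.19 (SE)). Of 13 imprinted fetal growth genes 4 fell (camera, adjusted p = 0.119), NNAT (-3.42) and MEST (-1.95) among them. Extracellular matrix genes went both ways, with 3 higher and 6 lower of 27, TNC at -3.62 ± 0.25 (SE) (median -0.11, camera's direction up; camera, adjusted p = 0.44).

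Among markers of other cells, 10 of 14 endothelial markers rose (camera, adjusted p = 3.2e-08, or 0.118 with estimated correlation), such as CLDN5 (1.62 ± 0.16 (SE)) and PECAM1 (1.59), and 4 of 19 leukocyte markers (camera, adjusted p = 5.8e-04, or 0.445 with estimated correlation), SLA-DRA by 3.81 and CD74 by 3.39. Of 14 adipocyte markers 5 rose and 3 fell (camera, adjusted p = 0.0051, or 0.445 with estimated correlation), FABP4 and PLIN4 (2.48) against SCD (-2.53). Of 11 nerve and Schwann cell markers 2 rose and 4 fell (camera, adjusted p = 0.644). The neuronal STMN2 and GAP43 (-3.27) and ERBB3 (-2.89) fell, and the list's median was 0.09 and its mean -0.53. Of 14 cartilage and bone markers 7 fell (camera, adjusted p = 0.0593) and of 7 tendon markers 3 (camera, adjusted p = 0.435), TNMD by 3.59. Of 10 erythroid markers 2 fell (camera, adjusted p = 0.193): HBA1 (-1.34) and the embryonic globin HBE1 (-3.04, but -0.84 and not called without the E33 libraries). Of the remaining lists, muscle protein breakdown genes (7 of 16 rose; camera, adjusted p = 3.1e-05, or 0.146 with estimated correlation), immediate early genes (8 of 16 rose; camera, adjusted p = 0.0051, or 0.445 with estimated correlation), glucocorticoid response genes (4 of 12 rose and 1 fell; camera, adjusted p = 0.015, or 0.445 with estimated correlation) and interferon response genes (5 of 15 rose and 1 fell; camera, adjusted p = 0.025, or 0.671 with estimated correlation) passed at the preset correlation. By limma, 2188 genes were called, 863 higher and 1325 lower in late gestation. Under median-ratio scaling 987 were higher and 825 lower, and after quantile normalisation 1024 were higher and 921 lower. Without the E33 libraries, 1904 genes were called. Leaving out the E33 libraries moved the counts of some lists (higher and lower genes) by over 1.5 times. Slow-fibre contractile genes went from 1 and 1 to 1 and 3. Interferon response genes went from 5 and 1 to 6 and 0. Cartilage and bone markers went from 0 and 7 to 1 and 5. Interferon response genes lost their list call with median-ratio scaling and quantile normalisation (adjusted p = 0.111 to 0.114). Cartilage and bone markers and developmental contractile genes passed as lists, lower, with median-ratio scaling, no filter, quantile normalisation and scaling to equal sums (adjusted p = 0.00772 to 0.0388). IGF and myostatin signalling genes, erythroid markers and imprinted fetal growth genes passed as lists, lower, with no filter (adjusted p = 0.0171 to 0.0406).

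Around birth, D0 was compared with the last fetal stage. PDK4, the kinase that shuts pyruvate out of oxidation, stood at 959.8 ± 563 FPKM (SD, n = 3) at D0 against 14.7 ± 5.51 (n = 3) at E105 (log2 fold change 5.75 ± 0.84 (SE), adjusted p = 4.8e-08). ANKRD1, a stretch-responsive protein of the sarcomere, stood at 611 ± 229 FPKM against 19.1 ± 8.85 (4.98 ± 0.76 (SE), adjusted p = 1.7e-07), FKBP5, a chaperone induced by glucocorticoids, at 39.98 ± 20.6 FPKM against 1.72 ± 0.291 (3.81 ± 0.37 (SE), adjusted p = 3.4e-13), and CTXN3 rose by 4.14 ± 0.26 (SE). COMP, a matrix protein of tendon and cartilage, had 5.003 ± 0.63 (SE), with 11.5, 214 and 15.2 FPKM in the 3 D0 libraries and 3.70 without replicate 2 of D0. The largest falls were those of FOS (-3.91 ± 0.84 (SE)), PRND (-3.56 ± 0.18 (SE)), TOP2A (-3.56 ± 0.28 (SE)), C4H1orf54 (-3.35) and TMSB15A (-3.32). MSTN fell from 40.6 ± 9.76 (n = 3) to 3.75 ± 1.18 FPKM (SD, n = 3) (-3.13 ± 0.30 (SE), adjusted p = 2.2e-13).

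Of 12 glucocorticoid response genes 7 rose (camera, adjusted p = 2.7e-06, or 0.278 with estimated correlation), with ZBTB16 at 2.20 ± 0.26 (SE) and TSC22D3 at 1.58. Of 12 heat shock genes 7 rose (camera, adjusted p = 3.2e-08, or 0.278 with estimated correlation): HSPB1 (2.72 ± 0.37 (SE)), CRYAB (2.67 ± 0.39 (SE)) and HSPB7 (2.40). Of 16 muscle protein breakdown genes 8 rose (camera, adjusted p = 1.3e-04, or 0.299 with estimated correlation), TRIM63 by 1.45 and FBXO40 by 1.37. Of 19 fatty acid oxidation genes 6 rose (camera, adjusted p = 2.0e-06, or 0.278 with estimated correlation), FABP3 by 1.74 and CPT2 by 1.33 besides PDK4. Of 34 oxidative phosphorylation and TCA cycle genes 3 rose (camera, adjusted p = 1.1e-08, or 0.426 with estimated correlation), IDH2 by 1.23 ± 0.20 (SE) the most. Under median-ratio scaling, 10 of the 34 were called higher. After quantile normalisation the other 2, IDH3A (0.93) and CYC1 (0.91), were not called, and CYC1 had 0.90 without replicate 2 of E105 and 0.82 without replicate 2 of D0, not called in either. Glycolysis and glycogen genes went both ways, with 2 higher and 2 lower of 19, such as PHKA1 (2.05) and PPP1R3C (-2.06) (camera, adjusted p = 0.111).

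Of 30 cell cycle genes 20 fell (camera, adjusted p = 7.4e-11, or 0.409 with estimated correlation), TOP2A from 18.6 ± 0.867 (n = 3) to 0.674 ± 0.221 FPKM (SD, n = 3) and KIF11 by 2.75. Of 14 endothelial markers 10 fell (camera, adjusted p = 3.9e-04, or 0.485 with estimated correlation), such as APLNR (-3.04 ± 0.34 (SE)) and CLDN5 (-2.44). Of 19 leukocyte markers 10 fell (camera, adjusted p = 0.135), such as SLA-DRA (-2.32). Of 10 erythroid markers 5 fell (camera, adjusted p = 0.295), HBB from 2881 ± 526 (n = 3) to 339.8 ± 33.1 FPKM (SD, n = 3). Of 11 nerve and Schwann cell markers 3 fell (camera, adjusted p = 0.0507), S100B (-1.60) and ERBB3 (-1.53) among them. Tendon markers had COMP alone called, of 7 (camera, adjusted p = 0.0832). Of 8 developmental contractile genes 5 fell (camera, adjusted p = 0.00892, or 0.299 with estimated correlation), with TNNT2 at -3.12 ± 0.29 (SE) and MYH8 at -1.60 ± 0.21 (SE), while of 15 fast-fibre contractile genes only ACTN3 was called (-1.89 ± 0.32 (SE); list median 0.01 and mean -0.18, camera, adjusted p = 0.698). MYH1, MYH2, MYH4, MYH3 and MYH7 were not called, with 0.31, 0.33, 0.03, -0.98 and -0.48.

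Myogenic regulators parted, with MYMK (-2.36 ± 0.23 (SE)), MYOG (-1.71 ± 0.20 (SE)) and MSC (-1.56) lower and MYF6 higher (1.37 ± 0.36 (SE)) of 14 (camera, adjusted p = 0.174). Against E100 in place of E105, MYF6 had 0.73 and was not called. PAX7, MYF5 and MYOD1 were not called (-0.64, -0.81 and -0.89). Of 17 IGF and myostatin signalling genes 6 fell (camera, adjusted p = 0.735), IGFBP5 (-2.11 ± 0.19 (SE)), FST (-1.76) and IGF1 (-1.73) besides MSTN. Of 27 extracellular matrix genes 6 fell and 1 rose (camera, adjusted p = 0.547), COL3A1 at -1.92 ± 0.25 (SE). Under median-ratio scaling, 3 matrix genes fell. Among 16 immediate early genes 4 fell (camera, adjusted p = 0.828), DUSP1 with -1.85. Adjusted over the list alone, counts differed for slow-fibre contractile genes (2 higher and 1 lower of 12 over all genes, 0 and 0 over the list), interferon response genes (3 lower of 15, 1 over the list) and cartilage and bone markers (2 lower of 14, 1 over the list), none of which passed as a list (adjusted p = 0.547, adjusted p = 0.922 and adjusted p = 0.735). Their medians were -0.25, -0.62 and -0.03, with camera's direction up for each. By limma, 1729 genes were called, 395 higher and 1334 lower at D0. Under median-ratio scaling 766 were higher and 803 lower, and after quantile normalisation 520 and 725. Leaving out replicate 1 or 2 of D0 gave 1543 and 2085 calls.

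Taking E100 in place of E105 moved the counts of some lists (higher and lower genes) by over 1.5 times. Fast-fibre contractile genes went from 0 and 1 to 2 and 1. Myogenic regulators went from 1 and 3 to 0 and 7. Extracellular matrix genes went from 1 and 6 to 1 and 11. Glycolysis and glycogen genes went from 2 and 2 to 2 and 1. Oxidative phosphorylation and TCA cycle genes went from 3 and 0 to 15 and 0. Fatty acid oxidation genes went from 6 and 0 to 12 and 0. Interferon response genes went from 0 and 3 to 0 and 5. Cartilage and bone markers went from 0 and 2 to 0 and 4. Tendon markers went from 1 and 0 to 1 and 2. Among glycolysis and glycogen genes, GPD1 lost its call without replicate 3 of E105 (-0.94), replicate 1 of D0 (-0.99) or replicate 3 of D0 (-0.99). Among slow-fibre contractile genes, MYL3 and MYOZ2 lost their calls without replicate 1 of E105 (1.27 and 1.42). MYL3 lost its call without replicate 2 of E105 (1.14) or replicate 2 of D0 (0.999). MYOZ2 lost its call without replicate 3 of D0 (1.37). MYL2 lost its call without replicate 1 of E105 (-1.42), replicate 2 of E105 (-1.35), replicate 3 of E105 (-1.02) or replicate 1 of D0 (-0.53). Among interferon response genes, IFI44 and IFI44L lost their calls without replicate 2 of E105 (-1.11 and -0.99) or replicate 1 of D0 (-1.13 and -0.98). Among cartilage and bone markers, SPP1 lost its call without replicate 1 of E105 (-1.91), replicate 2 of E105 (-1.83), replicate 1 of D0 (-1.91) or replicate 3 of D0 (-1.80). Among extracellular matrix genes, TNC lost its call without replicate 2 of D0 (0.39). After quantile normalisation PFKM (0.96), GPD1 (-0.97), MYL2 (-1.14), IFI44 (-0.85), IFI44L (-0.69), HAPLN1 (-0.87) and SPP1 (-1.70) also lost their calls, and 2 immediate early genes remained lower. Under median-ratio scaling GPD1 (-0.78), MYL2 (-0.95), IFI44 (-1.01), IFI44L (-0.86) and SPP1 (-1.68) did, and MYL2 and TNC when only the stages compared were fitted (adjusted p = 0.148 and 0.212). Leukocyte markers and nerve and Schwann cell markers passed as lists, lower, with median-ratio scaling, no filter, quantile normalisation and scaling to equal sums (adjusted p = 0.00958 to 0.0369). Myogenic regulators passed as a list, lower, with no filter (adjusted p = 0.0318). Tendon markers passed as a list, higher, with no filter (adjusted p = 0.0336). Extracellular matrix genes passed as a list, lower, with quantile normalisation (adjusted p = 0.0102).

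The first postnatal step compared D9 with D0. PVALB, a calcium buffer of fast fibres, rose by a log2 fold change of 6.37 ± 0.59 (SE), adjusted p = 2.1e-13. ACTN3 stood at 880.3 ± 127 FPKM (SD, n = 3) at D9 against 14.2 ± 7.78 (n = 3) at D0 (5.98 ± 0.32 (SE), adjusted p = 8.0e-23), MYH4 at 2936 ± 1345 FPKM against 353 ± 70.1 (2.95 ± 0.46 (SE)) and MYH1 at 4876 ± 545 FPKM against 1623 ± 206 (1.59 ± 0.27 (SE); 0.75 and not called with D20 in place of D9). Interferon-induced IFI6 (5.94 ± 0.77 (SE)) and ISG15 (5.92 ± 0.93 (SE)) and LGALS3BP, a secreted binder of galectins (4.68 ± 0.55 (SE)), followed. ISG15 had 28.4 FPKM in 1 library of D9 and 807 and 704 in the other 2. The largest falls were those of ANKRD1 (-4.87 ± 0.76 (SE)), COMP (-4.15 ± 0.63 (SE)), CTXN3 (-3.84 ± 0.26 (SE)), SMPDL3A (-2.89 ± 0.33 (SE)) and CSRP3, a muscle LIM protein (-2.79 ± 0.60 (SE)). The fall of COMP was -2.84 without replicate 2 of D0.

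Of 15 fast-fibre contractile genes 9 rose (camera, adjusted p = 1.3e-11, or 0.0665 with estimated correlation). Of 19 glycolysis and glycogen genes 14 rose (camera, adjusted p = 2.5e-15, or 0.0665 with estimated correlation), LDHA from 90.03 ± 36.7 (n = 3) to 1041 ± 145 FPKM (SD, n = 3) and GPD1 by 3.19. Of 16 excitation-contraction coupling genes 6 rose (camera, adjusted p = 2.9e-07, or 0.0833 with estimated correlation), such as the calcium release channel RYR1 (1.45 ± 0.18 (SE)). Under median-ratio scaling, 11 coupling genes were higher. Of 12 slow-fibre contractile genes 5 rose and 2 fell (camera, adjusted p = 0.00822, or 0.611 with estimated correlation), TNNT1 by 2.47 ± 0.57 (SE). MYH7 rose (2.02 ± 0.57 (SE)), with 1.37 and no call without replicate 1 of D0, and under median-ratio scaling 10 slow-fibre genes were higher and 0 lower. When only the stages compared were fitted, MYH7, MYL2 and TNNC1 lost their calls (adjusted p = 0.0659, 0.0574 and 0.0659), 3 of the 5 rises. Of 8 developmental contractile genes 2 rose (camera, adjusted p = 0.035, or 0.374 with estimated correlation), TNNT2 by 2.56 ± 0.29 (SE). MYH8, MYH2 and MYH3 were not called (-0.80, 0.04 and -0.15, the last 0.13 under median-ratio scaling and quantile normalisation). MSTN rose to 18.4 ± 4.86 FPKM (SD, n = 3) (2.03 ± 0.30 (SE)), and IGFBP5 by 1.61, with 3 of 17 IGF and myostatin signalling genes higher and 2 lower (median -0.32, camera's direction up; camera, adjusted p = 0.751).

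Of 30 cell cycle genes 18 rose (camera, adjusted p = 7.8e-17, or 0.234 with estimated correlation), TOP2A by 2.95 ± 0.28 (SE). All 15 interferon response genes rose (camera, adjusted p = 6.8e-11, or 0.234 with estimated correlation), MX1 by 3.61, together with 13 of 19 leukocyte markers (camera, adjusted p = 1.3e-10, or 0.234 with estimated correlation), SLA-DRA by 3.18 ± 0.33 (SE) and C1QB by 2.63, 5 of 10 erythroid markers (camera, adjusted p = 0.00433, or 0.482 with estimated correlation), HBB by 2.43, and 3 of 14 endothelial markers (camera, adjusted p = 1.9e-04, or 0.39 with estimated correlation), APLNR by 2.18. Under median-ratio scaling, 5 of the endothelial markers were higher. Of 14 adipocyte markers 4 rose (camera, adjusted p = 0.00506, or 0.537 with estimated correlation), PLIN4 by 1.17 ± 0.29 (SE) and SCD by 2.80 (1.19 and not called with D20 in place of D9). Of 12 heat shock genes 8 fell (camera, adjusted p = 0.00742, or 0.516 with estimated correlation), CRYAB from 645 ± 225 (n = 3) to 102 ± 24.7 FPKM (SD, n = 3) and the mitochondrial chaperone HSPD1 by 1.77. Of 12 glucocorticoid response genes 4 fell (camera, adjusted p = 0.162), FKBP5 with -2.62 ± 0.37 (SE). Of 16 muscle protein breakdown genes 8 fell and 1 rose (camera, adjusted p = 0.0465, or 0.587 with estimated correlation): FBXO32 (-2.29) and GABARAPL1 (-1.72) were lower and FBXO40 (2.91 ± 0.20 (SE)) higher.

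Of 38 ribosomal protein genes 12 fell (camera, adjusted p = 1.4e-13, or 0.365 with estimated correlation), RPL3 with -1.74 ± 0.16 (SE) and RPS12 with -1.50. Under median-ratio scaling 3, and after quantile normalisation 6, ribosomal protein genes fell. Of 13 imprinted fetal growth genes PEG10 (-2.42 ± 0.24 (SE)) and MEG3 (-1.71) fell (camera, adjusted p = 0.115), while IGF2 was not called (-0.04). Of 14 myogenic regulators 2 rose, MSC (1.26) and MYMK (1.004; 0.86 without replicate 1 of D0 and 0.80 without replicate 1 of D9, not called in either), and MYF6 fell (-1.29 ± 0.36 (SE), but -0.91 and not called after quantile normalisation; camera for the list, adjusted p = 0.362). Adjusted over the list alone, counts differed for immediate early genes (1 higher of 16 over all genes, 0 over the list; camera, adjusted p = 0.213) and cartilage and bone markers (3 lower of 14, 1 over the list; camera, adjusted p = 0.971). By limma, 1482 genes were called, 709 higher and 773 lower at D9. Under median-ratio scaling 1075 were higher and 375 lower, after quantile normalisation 843 and 349, and with all libraries scaled to equal sums 1221 and 830. Leaving out replicate 1 or 2 of D0 gave 1268 and 1829 calls.

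Taking D20 in place of D9 moved the counts of some lists (higher and lower genes) by over 1.5 times. Developmental contractile genes went from 2 and 0 to 1 and 2. Myogenic regulators went from 2 and 1 to 2 and 2. Ribosomal protein genes went from 0 and 12 to 0 and 5. Immediate early genes went from 1 and 0 to 0 and 1. Among developmental contractile genes, MYL4 lost its call without replicate 1 of D0 (0.95) or replicate 2 of D9 (0.97). Among slow-fibre contractile genes, MYH7 and TNNC1 lost their calls without replicate 1 of D0 (1.37 and 1.33). Among IGF and myostatin signalling genes, IGFBP3 lost its call without replicate 1 of D0 (-0.90). Among adipocyte markers, ADIPOQ and DGAT2 lost their calls without replicate 3 of D0 (1.17 and 1.19), replicate 2 of D9 (1.68 and 1.48) or replicate 3 of D9 (1.12 and 0.90). Among cartilage and bone markers, COL2A1, COL11A1 and COL11A2 lost their calls without replicate 2 of D0 (-0.37, -0.46 and -1.09). COL2A1 and COL11A1 lost their calls without replicate 2 of D9 (-1.12 and -0.94). Among immediate early genes, FOS lost its call without replicate 2 of D0 (1.81), replicate 3 of D0 (1.81), replicate 2 of D9 (1.43) or replicate 3 of D9 (1.12). When only the stages compared were fitted, ADIPOQ, DGAT2, COL2A1, COL11A1, COL11A2 and FOS also lost their calls (adjusted p = 0.112 to 0.275). With no filter ADIPOQ, DGAT2 and FOS did (0.0532 to 0.0731). Muscle protein breakdown genes lost their list call with a mean of at least 1 FPKM and quantile normalisation (adjusted p = 0.0841 to 0.0861). Developmental contractile genes lost their list call with median-ratio scaling and a pseudocount of 0.1 (adjusted p = 0.0512 to 0.0513). Glucocorticoid response genes and imprinted fetal growth genes passed as lists, lower, with no filter (adjusted p = 0.00706 to 0.0178).

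The late postnatal stages (D140 to D180) were compared with the early ones (D20 to D40). MSS51, a mitochondrial protein of muscle, rose from 2.53 ± 2.52 (n = 9) to 34.1 ± 19.1 FPKM (SD, n = 9) (log2 fold change 3.38 ± 0.30 (SE), adjusted p = 2.1e-14), TEX9 from 7.36 ± 1.95 to 45.7 ± 16.8 FPKM (2.44 ± 0.14 (SE), adjusted p = 1.2e-21), and GPR157 (1.94), PPP1R14C (1.89) and PGM2L1 (1.77) by less. Among the largest falls were those of ACTC1, from 77.1 ± 68.9 to 8.50 ± 2.73 FPKM (-2.66 ± 0.20 (SE), adjusted p = 7.5e-17), ART3 (-2.64 ± 0.14 (SE)), the lipid droplet protein PLIN5 (-2.40 ± 0.17 (SE)) and POSTN (-2.03). IGF2 fell from 32.8 ± 15.7 (n = 9) to 9.41 ± 6.59 FPKM (SD, n = 9) (-1.78 ± 0.19 (SE), adjusted p = 1.1e-11) and was the only call among 13 imprinted fetal growth genes (camera, adjusted p = 2.0e-05, or 0.0849 with estimated correlation).

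Of 12 slow-fibre contractile genes 10 fell (camera, adjusted p = 5.2e-04, or 0.398 with estimated correlation), such as the Z-disc protein MYOZ2 (-2.24 ± 0.34 (SE)) and CASQ2 (-2.15). MYH7 had -1.27 ± 0.33 (SE), and -0.94 with no call without replicate 1 of D160. In replicate 2 of D160 it stood at 2232 FPKM, against 81.1 and 180.4 in the other 2 libraries, and MYH4 at 404.6 against 3561 and 6071. Of 15 fast-fibre contractile genes PVALB alone was called (1.32, but 0.92 and not called without the 3 libraries of D30; camera for the list, adjusted p = 0.00864, or 0.411 with estimated correlation). MYH1, MYH2, MYH4, MYH3 and MYH8 were not called (0.28, -0.21, 0.35, -0.45 and 0.34). Of 19 fatty acid oxidation genes 7 fell (camera, adjusted p = 9.5e-12, or 0.0748 with estimated correlation), PDK4 with -3.61 ± 0.48 (SE) and CPT1B with -1.77 ± 0.12 (SE). Of 34 oxidative phosphorylation and TCA cycle genes 3 fell (camera, adjusted p = 2.6e-16, or 0.177 with estimated correlation), NDUFV1 (-1.12 ± 0.091 (SE)), COX4I1 and COX7A1. After quantile normalisation COX4I1 (-0.98) and COX7A1 (-0.89) were not called. COX7A1 was not called either under median-ratio scaling (-0.96), without the D30 libraries (-0.99), or without replicate 2 of D40 (-0.95), replicate 1 of D160 (-0.93) or replicate 3 of D180 (-0.96). None of 19 glycolysis and glycogen genes was called by limma, with 12 at an unadjusted p below 0.05 (median 0.35; camera, adjusted p = 5.1e-04, or 0.361 with estimated correlation). Of 8 developmental contractile genes 2 fell, ACTC1 among them (camera, adjusted p = 0.0229, or 0.361 with estimated correlation).

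Of 14 adipocyte markers 7 rose (camera, adjusted p = 0.00118, or 0.361 with estimated correlation), with the desaturase SCD at 3.96 ± 0.34 (SE) and the fatty acid synthase FASN at 2.996 ± 0.26 (SE). Of 12 heat shock genes 4 rose (camera, adjusted p = 1.1e-04, or 0.36 with estimated correlation), HSP70.2 by 2.22 ± 0.33 (SE) and HSPH1 by 1.55. Of 16 immediate early genes 2 rose (camera, adjusted p = 0.0136, or 0.459 with estimated correlation), with FOS at 1.80 ± 0.49 (SE). Of 11 nerve and Schwann cell markers 4 fell (camera, adjusted p = 3.5e-04, or 0.177 with estimated correlation), MBP (-1.59 ± 0.13 (SE)) and PMP22 (-1.17) among them. Of 10 erythroid markers 4 fell (camera, adjusted p = 0.0191, or 0.459 with estimated correlation), HBB by 1.85. Of 15 interferon response genes 6 fell (camera, adjusted p = 0.00877, or 0.512 with estimated correlation), IFI6 with -1.60 ± 0.44 (SE). Of 9 liver markers 3 fell (camera, adjusted p = 0.00235, or 0.361 with estimated correlation), ALB with -1.93 ± 0.32 (SE), but ALB had -0.51 without the libraries of D30, and none of the 3 was then called. Of 27 extracellular matrix genes 3 fell (camera, adjusted p = 0.00318, or 0.493 with estimated correlation), POSTN, FBN2 (-1.78) and MFAP4 (-1.48). Of 12 neuromuscular junction genes 2 fell (camera, adjusted p = 0.00679, or 0.36 with estimated correlation), CHRNA1 with -1.11. By limma, 0 of 30 cell cycle genes were called and 27 had an unadjusted p below 0.05 (median -0.51; camera, adjusted p = 5.4e-08, or 0.361 with estimated correlation), while without the D30 libraries 11 were called lower. Of 14 endothelial markers 0 were called and 13 had an unadjusted p below 0.05 (median -0.51; camera, adjusted p = 5.2e-04, or 0.361 with estimated correlation). Of 38 ribosomal protein genes 0 were called and 23 had an unadjusted p below 0.05 (median -0.20; camera, adjusted p = 0.00144, or 0.53 with estimated correlation). Of 19 leukocyte markers 0 were called and 8 had an unadjusted p below 0.05 (median 0.27; camera, adjusted p = 0.0274, or 0.556 with estimated correlation). Of 15 circadian clock genes 0 were called and 9 had an unadjusted p below 0.05 (median 0.19; camera, adjusted p = 0.0129, or 0.36 with estimated correlation).

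MYOD1 fell (-1.13 ± 0.14 (SE)), the only call among 14 myogenic regulators (median -0.09, camera's direction up; camera, adjusted p = 0.891), and PAX7, MYF5, MYOG and MYF6 were not called (-0.31, -0.60, -0.34 and 0.90). MSTN rose from 17.995 ± 9.75 (n = 9) to 39.1 ± 14.99 FPKM (SD, n = 9) (1.10 ± 0.17 (SE)) alone of 17 IGF and myostatin signalling genes (median -0.28, camera's direction down; camera, adjusted p = 0.0474, or 0.361 with estimated correlation), but was not called without replicate 1 of D160 (0.97), without replicate 2 of D140 (0.996) or after quantile normalisation (0.96). Of 16 muscle protein breakdown genes TRIM63 rose (1.17 ± 0.18 (SE); camera for the list, adjusted p = 0.0832). Of 12 glucocorticoid response genes ANGPTL4 (-1.33) and CEBPD fell (camera, adjusted p = 0.0474, or 0.493 with estimated correlation), the latter not called without the D30 libraries (-0.85). By limma, 324 genes were called, 112 higher and 212 lower in the late stages, and 342 were called without the D30 libraries. Leaving out the D30 libraries moved the counts of some lists (higher and lower genes) by over 1.5 times. Neuromuscular junction genes went from 0 and 2 to 0 and 1. Myogenic regulators went from 0 and 1 to 1 and 1. Immediate early genes went from 2 and 0 to 4 and 0. Heat shock genes went from 4 and 0 to 2 and 0. Circadian clock genes went from 0 and 0 to 1 and 0. Among developmental contractile genes, MYL6B lost its call without replicate 2 of D140 (-0.98), replicate 1 of D160 (-0.88) or replicate 3 of D160 (-0.96). Among heat shock genes, DNAJB1 and CRYAB lost their calls without replicate 2 of D20 (0.95 and 0.94), replicate 2 of D140 (0.93 and 0.96) or replicate 3 of D180 (0.93 and 0.94). Among immediate early genes, FOSB lost its call without replicate 2 of D20 (0.98), replicate 2 of D40 (0.96), replicate 3 of D40 (0.999), replicate 2 of D140 (0.98) or replicate 2 of D180 (0.87). Among liver markers, FGA and FGB lost their calls without replicate 1 of D20 (-0.83 and -0.94). MYL6B also lost its call when only the stages compared were fitted (adjusted p = 0.106). IGF and myostatin signalling genes lost their list call with a mean of at least 1 FPKM and scaling to equal sums (adjusted p = 0.0521 to 0.0527). Glucocorticoid response genes lost their list call with a mean of at least 1 FPKM, a pseudocount of 0.1 and scaling to equal sums (adjusted p = 0.0565 to 0.0935). Immediate early genes, leukocyte markers and liver markers lost their list calls with a mean of at least 1 FPKM (adjusted p = 0.0566 to 0.155). Fast-fibre contractile genes and ribosomal protein genes lost their list calls with quantile normalisation (adjusted p = 0.0776 to 0.153). Muscle protein breakdown genes passed as a list, higher, with no filter (adjusted p = 0.0311). Over the 5 comparisons, 81 list tests passed at the preset correlation and 10 of them held with an estimated correlation. Of these 10, 6 were of postnatal against prenatal and 4 of late against early fetal.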

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

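The alternatives that scale without the 2 most abundant noncoding loci, leave out or replace a stage (D0, E33, D30, E100 for E105, D20 for D9) were chosen after the data were seen. The others were fixed beforehand. Leaving out each library in turn kept these counts within 1.5 times their value: 3733 to 3826 for postnatal against prenatal, 2141 to 2238 for late against early fetal, 1543 (without replicate 1 of D0) to 2085 (without replicate 2) for D0 against E105, 1268 to 1829 (without the same libraries) for D9 against D0, 298 to 364 for late against early postnatal, 13951 to 14124 for the F test and 5707 to 6840 for the adjacent steps. Where a stage kept 2 libraries, its spread was taken from all stages. With the replicate number as a replicate block the counts were 3781, 2188, 1727, 1481 and 324 for the 5 comparisons in this order, 14118 for the F test, 6096 for the steps and 81 for the list tests, so the block changed no call of a list and no count by over 1.5 times. The numbers did not pair the libraries: deviations from the stage means correlated at 0.0041 on average over 1053 pairs with the same number, of which 240 exceeded 0.1, against -0.0020 for other pairs, and 28 of 81 libraries correlated best with their own number.

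Counts depended on the pseudocount and on the fold change asked. With a pseudocount of 0.1, which weighs low genes more by construction, calls were 6639, 3726, 3531, 2775 and 898 for the 5 comparisons and 13100 for the steps. With no fold change asked they were 13337, 10715, 7582, 7381, 6431 and 38837. Median-ratio scaling gave 2411 and quantile normalisation 2211 calls for postnatal against prenatal. Equal sums gave 520 for late against early postnatal and 9322 for the steps, and scaling without the 2 noncoding loci gave 2264 for D9 against D0, 537 for late against early postnatal and 10372 for the steps. Both raise all values, and only the second let in more genes. Counts of single adjacent steps moved by over 1.5 times in 99 checks with an alternative and in 24 with a library left out. With an estimated correlation 10 list tests passed in place of 81. The other counts of these comparisons moved by less than 1.5 times, among them those without the D0 (4088), E33 (1904) or D30 (342) libraries, with E100 in place of E105 (1987) and with D20 in place of D9 (1508).

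Of the calls of named genes, counted per comparison, 25 were lost after quantile normalisation, 23 under median-ratio scaling and 18 (of 15 genes) when only the stages compared were fitted. Leaving out a library ended a call in 100 checks and made a call in 10, while 13239 did not change. No called gene changed sign. Anchor genes that were not called changed sign as follows, and the cause was not tested. IGF2 had 0.046 for D0 against E105 under median-ratio scaling, 0.24, 0.046 and 0.18 for D9 against D0 under median-ratio scaling, equal sums and quantile normalisation, and -0.040 for late against early fetal without the E33 libraries. MYH3 had 0.13 and 0.13 for D9 against D0 under median-ratio scaling and quantile normalisation, MYH4 -0.041 for D0 against E105 under quantile normalisation, and MYH2 -0.67 with D20 in place of D9. With a library left out, the log2 fold change ranged from -0.049 to 0.085 for MYOD1 in late against early fetal. For D0 against E105 it ranged from -1.14 (without replicate 2 of D0) to 0.18 (without replicate 1) for MYH7 and from -0.12 to 0.17 for MYH4. For D9 against D0 it ranged from -0.57 to 0.23 for MYH3, -0.36 to 0.36 for MYH2, -0.024 to 0.35 for MYOG and -0.14 to 0.080 for IGF2. The direction of 33 list tests, none called in either setting, changed; their medians were, with median-ratio scaling, IGF and myostatin signalling genes (D9 against D0) -0.14, cartilage and bone markers (D0 against E105) -0.041, fatty acid oxidation genes (D9 against D0) 0.087, interferon response genes (D0 against E105) -0.45, liver markers (D0 against E105) -0.048, nerve and Schwann cell markers (late fetal against early fetal) 0.90; with no filter, IGF and myostatin signalling genes (D9 against D0) -0.29, cartilage and bone markers (D0 against E105) -0.093, epidermis markers (D9 against D0) 0.013, excitation-contraction coupling genes (D0 against E105) -0.21, interferon response genes (D0 against E105) -0.62, nerve and Schwann cell markers (late fetal against early fetal) -0.075, oxidative phosphorylation and TCA cycle genes (D9 against D0) -0.10, ribosomal protein genes (D0 against E105) -0.11; with equal sums, cartilage and bone markers (D0 against E105) -0.035, interferon response genes (D0 against E105) -0.79, liver markers (D0 against E105) -0.13, myogenic regulators (late postnatal against early postnatal) -0.092; with a mean of at least 1 FPKM, circadian clock genes (D0 against E105) -0.40, circadian clock genes (D9 against D0) -0.18, fatty acid oxidation genes (D9 against D0) -0.19, liver markers (D0 against E105) -0.44, nerve and Schwann cell markers (postnatal against prenatal) -0.33; with quantile normalisation, excitation-contraction coupling genes (D0 against E105) -0.14, extracellular matrix genes (late fetal against early fetal) -0.027, fast-fibre contractile genes (D0 against E105) -0.041, fatty acid oxidation genes (D9 against D0) 0.072, interferon response genes (D0 against E105) -0.26, liver markers (D0 against E105) -0.0091, myogenic regulators (late postnatal against early postnatal) -0.061, ribosomal protein genes (D0 against E105) -0.001, slow-fibre contractile genes (D0 against E105) -0.32; with a pseudocount of 0.1, interferon response genes (D0 against E105) -1.07. The depth is unknown, so its limit on these values could not be assessed.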

Other observations

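The lists and tests for D60 and D30 were chosen after values at those stages had been seen. The prediction for the 35 further liver genes was written before their values were looked at. Leaving out a D60 library was chosen after the result for D60 was seen.

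Interferon response and immune transcripts differed between libraries of the same stage. At E60, ISG15 had 245 FPKM in replicate 3 and 0.732 and 1.11 in the other libraries, and IFI6 had 698.0 against 9.88 and 12.7. At D80, CXCL9 stood at 191, 94.2 and 10.2 FPKM in the 3 libraries, CXCL10 at 109, 80.3 and 16.7, and JCHAIN at 276.0, 32.6 and 13.2. In the library of D0 with the highest COMP (214 FPKM), the tendon marker TNMD was also highest, at 75.4 FPKM against 6.03 and 9.96. Of 2 abundant noncoding loci, LOC106509199 averaged 13171 FPKM and ranged from 708 to 42511 between libraries, and XLOC_113201 averaged 3134 and ranged from 8.03 to 16116.

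Of the genes called between E105 and D0, 651 were called in the opposite direction between D0 and D9, 255 higher at D0 and 396 lower, while 12 were called in the same direction in both. Independent lists would share 87.98 by chance. Median-ratio scaling gave 705 genes, and the fewest without a D0 library were 545 (without replicate 1; 858 without replicate 2), which argues against the scaling or a single library as the whole cause. Both comparisons use the 3 D0 libraries, and their fold changes correlated at -0.65 across genes. Their covariance of -0.29 was stronger than simulated library spread gave (mean -0.018 in 100 draws of unchanged stages sharing the D0 libraries). Those draws hold few calls, so their highest of 0 opposite calls decides nothing. A shift common to the 3 D0 libraries may contribute and cannot be split from the stage. Of the 651 genes, 573 were not called between E105 and D9. A batch of the D0 libraries, absent from the labels, and the state of the newborn both remain open.

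A list of amino acid response genes was written with values at D60 in view, and its enrichment was not tested. Of the 42 genes measured, 21 were called higher at D60 than at D40 and 0 lower. The others, such as NUPR1 (-0.68) and DDIT4 (0.12), were not called. Median-ratio scaling gave 21, and the fewest without a D60 library were 16 (without replicate 2). Some, not all, of the 21 calls thus rested on 1 library. ATF5 stood at 80.1 ± 2.60 FPKM (SD, n = 3) at D60 and 3.50 ± 1.20 at D40, and ASNS, an asparagine synthetase, at 47.0 ± 23.3 at D60 against 7.04 ± 3.57 at D40. Around birth, 20 of the 42 were called higher and 0 lower at D0 than at E105. At D9, 0 were called higher and 20 lower than at D0. No biological explanation was tested, as the labels give only the stage.

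At D30, liver transcripts may have entered the libraries. ALB, the main plasma protein made by the liver, stood at 28.2, 21.99 and 49.5 FPKM in the 3 libraries and at most 0.223 at D40. Of 35 further liver genes, 31 were above every D40 library in all 3 D30 libraries (88.6%, against 14.2% of all genes and 5% by chance), and the ratio of ALB to FGB was similar in these libraries (4.53, 4.16 and 4.65) and in replicate 1 of D20 (3.48). This is consistent with RNA or reads from liver in those libraries; a rise of these genes in muscle itself was not tested. APOA1, with 29.9, 37.6 and 41.0 FPKM at D30 and 35.4, 39.0 and 55.7 at D40, was not higher.

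Other splits of the same libraries were drawn to ask whether grouping alone could give as many calls. Of 100 shuffles of the stages, the real one included, 1 gave as many genes as the F test's 14120 (highest other 8032). For the 3781 of postnatal against prenatal it was also 1 (highest other 0). For late against early fetal (2188, highest other 566) and late against early postnatal (324, highest other 176), 1 of 100 shuffles gave as many. Assigning single libraries to stages at random therefore did not give these counts. The shuffles broke up the libraries of a stage, which adds spread within stages, so chance among whole stages was not tested. For the adjacent steps, 5 of 100 gave as many as 6093, with a highest other of 17902, since shuffling sets prenatal beside postnatal libraries; by this test chance was not excluded, and it points to the structure of the samples. For D0 against E105 (1729, highest other 234) and D9 against D0 (1482, highest other 272), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.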
